A study of Mus musculus with 15 samples.

How the data were processed

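Total RNA of mouse left ventricle was extracted with TRIzol, treated with DNase and made into libraries with an Illumina TruSeq total RNA Gold kit, per the labels' protocols. Per the submitters' processing notes, reads were demultiplexed with bcl2fastq 2.20.0.422, trimmed with Trimmomatic 0.39 and aligned with STAR 2.7.4a to mm39, the GRCm39 build. The authors deposited raw counts per gene symbol in separate tables for WT, the G-line and the A-line, each with the same 40174 symbols. The values were whole numbers and were used as deposited. The counting program, the annotation and whether counting used strand are not given in the sources used here. Reads of a gene and its antisense partner, such as Hopx and Hopxos, can therefore not be told apart. Genes with near-identical copies, such as Myh6 and Myh7, Hspa1a and Hspa1b or the globin genes, are uncertain in how reads were divided between them.

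Groups and replicate numbers came from the sample titles. Columns were compared before any test: A-line HOM replicates 2 and 3 were identical to WT replicates 2 and 3 in every symbol. Each such library was counted once, under WT. This choice was made after the data were seen and after results under it had been computed, and the labels do not decide it, so all results were also computed with the pair as A-line HOM, left out, or in both groups. The main analysis thus departed from the planned 15 libraries and used 13. No group was taken from expression values. All 13 libraries had Y-linked counts above Xist, so the planned sex covariate had nothing to separate.

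Genes were kept when at least 3 libraries reached the CPM that 10 counts make in the median library (0.422 CPM) and the total was at least 15 counts, a rule written out from edgeR's expression filter since 1 group held a single library. It left 17588 genes. Counts were scaled by edgeR 4.0.16's TMM factors, and CPM values in the text were computed here with them from the deposited counts. One model with a mean per group and a spread shared by all 13 libraries (8 residual degrees of freedom, common biological variation 17.1%) was fitted with edgeR's robust quasi-likelihood method. Each comparison was tested with its quasi-likelihood F test, two-sided, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. Adjusted p-values of genes come from this test unless another tool is named, and log2 fold changes are given ± SE. A gene without a count in a group was set to a floor of 3 counts over the group. Intervals and floors cover counting error only.

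Beforehand 24 gene lists and 16 marker lists of other cell types were fixed. Of these 40 lists 38 could be tested: 1, of mitochondrially encoded genes, had no member in the tables and 1 had too few genes past the filter. The list called respiratory chain holds nuclear-encoded genes only. Lists were tested with camera (limma 3.58.1, R 4.3.3) at the preset correlation of 0.01, Benjamini-Hochberg adjusted over the lists of a comparison, and again with an estimated correlation and with fry. Adjustment of single genes was repeated over each list alone. The lists, tests and the rule for named genes were written before the data were examined. In each comparison the rule took genes with an adjusted p under 0.05, a mean of at least 1 CPM over both groups and libraries that did not overlap, a separation that chance gives in 10% of genes for 3 against 3 and in 50% for the 1 A-line HOM library against 3. It named the 10 with the highest and the 10 with the lowest log2 fold change (5 and 5 where no WT was compared), leaving out predicted or clone-named genes, read as including LOC symbols, and Xist, Tsix and Y-linked genes. It added Rbm20, up to 4 members of each called list by smallest adjusted p, up to 2 of each list not called as values, and 14 textbook remodelling genes in the HOM comparisons with WT. The values of some genes that the rule took are not reported here.

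Alternatives planned beforehand were DESeq2 1.42.0, its size factors (RLE) in edgeR, no filter beyond 1 count, at least 1 CPM in at least 3 libraries, only the compared groups, the replicate number as a block, omission of mitochondrial, ribosomal RNA, Xist and Y-linked genes, and leaving out each library. Chosen after seeing the data were the 3 other treatments of the shared pair and the omission of 3 libraries with atrial transcripts (Myl7 at 10 CPM or more) or of 2 with shifted clock genes (Arntl at 20 CPM or more). Similarity of the lines was set beside 20 simulations of unchanged groups that share a simulated WT group. Every one of the 13 libraries, WT included, was drawn anew around 1 mean per gene.

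The procedure was tested on simulated data with 200 changed genes. For G-line HOM against WT it recovered 60.8% of genes changed by a log2 fold of 1 and 86.9% of those changed by 2, with 9 false among 154 calls in 17150 genes. For A-line HOM against WT, with its single library, it recovered 52.1% and 74.7%, with 5 false among 129 calls in 17123 genes, and for A-line HET against G-line HET 57.1% and 81.6%, with 6 false among 142 calls in 17160 genes. A RefSeq table of assembly GRCm38.p6, another build than the authors', served only for gene names and chromosomes. It matched 38684 of the 40174 symbols, and no coordinates are given.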

Results

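Gene expression was measured by total RNA sequencing of the left ventricle of 2-month-old C57BL/6 mice. The mice carried point mutations in Rbm20, which encodes a muscle RNA-binding protein that regulates the splicing of titin and other cardiac transcripts. The S639G allele is called the G-line here and the S637A allele the A-line, and heterozygous (HET) and homozygous (HOM) samples of each stood beside wild type (WT). The series asks by which mechanisms these mutations act in cardiac remodelling. The labels name 5 groups of 3 libraries, 15 in all. The columns of A-line HOM replicates 2 and 3 held the same count as those of WT replicates 2 and 3 in every one of 40174 gene symbols, so 13 distinct libraries remained. Each identical pair was counted once, as WT, which left 3 WT, 3 G-line HET, 3 G-line HOM, 3 A-line HET and 1 A-line HOM library. The labels do not decide which name is right for the 2 shared libraries, and every comparison with WT or A-line HOM rests on this choice.

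Total counts per library lay between 25279202 and 26549906 in WT, 23714906 and 28121438 in G-line HET and 20324529 and 29436407 in G-line HOM. The A-line was sequenced less deeply, with 12959087 to 17448328 counts in A-line HET and 17507813 in the A-line HOM library. Mitochondrial ribosomal RNA, a transcript class whose share can vary with library preparation, took 20.2 to 23.4% of the counts in WT, 15.4 to 16.7% in G-line HET, 10.8 to 13.5% in G-line HOM and 13.2 to 17.1% in A-line HET. It took 15.1% in the A-line HOM library (95% Clopper-Pearson interval 15.09% to 15.13%, for counting error only). Ttn, the gene of the giant sarcomere protein titin, took 7.84 to 8.74% of the counts in WT and 10.1 to 11.6% in the mutant libraries. The labels do not say whether the libraries of a group came from separate animals, so p-values measure the spread between these samples, which may be technical. The single A-line HOM library was assumed to vary like the libraries of the other groups.

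Rbm20 itself was expressed in every library. Its level in CPM, counts scaled to a common library size, was 395 ± 33.5 (SD, n = 3) in WT, 388 ± 18.4 in G-line HET, 391 ± 29.8 in G-line HOM and 412 ± 30.2 in A-line HET, and 495.5 in the A-line HOM library. Single libraries lay between 356.9 and 495.5 CPM, and no comparison called Rbm20 (edgeR quasi-likelihood test, adjusted p = 0.932 for G-line HOM, 0.907 for G-line HET, 0.775 for A-line HET and 0.195 for A-line HOM against WT). The alleles are point mutations, so the level of Rbm20 does not check the labels.

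Some libraries held transcripts of other origin or state. Sln and Myl7, which mark atrial muscle, stood at 155 and 524 CPM in WT replicate 2, 57.5 and 240 CPM in A-line HET replicate 3 and 7.54 and 45.8 CPM in G-line HOM replicate 1, and Myl7 did not exceed 3.43 CPM elsewhere. These libraries also held the fat-cell gene Adipoq, at 11.01, 3.085 and 3.159 CPM in that order. They held the mesothelial gene Upk3b at 1.4, 5.318 and 3.316 CPM. Ucp1, a gene of brown fat, was at 17.9 CPM in WT replicate 2. Arntl, a core gene of the circadian clock, was at 24.6 CPM in G-line HOM replicate 1 and 29.04 CPM in A-line HET replicate 2 against 1.17 to 5.28 CPM in the other libraries. The A-line HOM library stood out in immediate-early transcripts, with Atf3 at 115 CPM, Jun at 61.0 CPM and Egr1 at 45.9 CPM. The adult beta-globin gene Hbb-bt was at 88.0 and 106 CPM in G-line HOM replicates 1 and 2 and between 20.1 and 55.3 CPM in the other libraries.

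Homozygous G-line hearts were compared with WT to ask what the S639G allele does in both copies. Several cardiomyocyte genes were almost absent. Myh7b, a slow-type myosin heavy chain gene, was at 0.199 ± 0.0506 CPM (SD, n = 3) against 66.9 ± 10.3 in WT, a log2 fold change of -8.34 ± 0.36 (SE; adjusted p = 2.09e-07). Hopx, a homeodomain-only regulator of heart muscle, was at 1.79 ± 0.447 against 138 ± 13.6 CPM (-6.29 ± 0.33, adjusted p = 2.86e-06). The sodium channel subunit gene Scn4b was at 0.308 ± 0.258 against 44.5 ± 9.36 CPM (-7.14 ± 0.89, adjusted p = 0.000519). Strit1, whose micropeptide activates the sarcoplasmic reticulum calcium pump, had no count in G-line HOM against 5.59 ± 0.951 CPM, at least 138.7-fold lower. The G protein signalling regulator Rgs13 was at least 88.1-fold lower, both against a floor of 3 counts over the group. The water channel gene Aqp4 was at 0.0104 CPM against 9.70 ± 1.96. Lgi1, Acsm5, Pde11a and Cngb3 also fell, by log2 fold changes of -6.95, -6.87, -6.85 and -6.45.

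Casq1, the skeletal-muscle calsequestrin gene, rose from 11.2 ± 4.56 to 298.5 ± 56.7 CPM in G-line HOM (4.74 ± 0.32, adjusted p = 1.16e-05). The wall-stress genes Ankrd1 (3.32 ± 0.20, adjusted p = 6.98e-07) and Nppb, the B-type natriuretic peptide gene (2.83 ± 0.24, adjusted p = 2.41e-05), rose. The matricellular gene Postn rose from 62.9 ± 33.5 to 488 ± 148 CPM (2.96 ± 0.53, adjusted p = 0.00341). The highest fold changes belonged to genes near 0 in WT. Tent5b rose by 5.36 ± 0.66 to 15.7 ± 6.11 CPM, Kctd16 by 4.80 ± 0.70 to 33.2 ± 8.95 CPM, and Mylk2, the skeletal myosin light chain kinase gene, by 6.11 ± 0.72 to 5.03 ± 3.27 CPM. Chodl stood at 5.35 ± 2.98 against 0.0126 CPM and Ptx4 at 2.61 ± 1.46 against 0.0126 CPM. Grin2a, Ereg, Rasgef1a, Mgat5b and Add2 rose by log2 fold changes of 5.40, 5.33, 5.26, 5.24 and 5.21.

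Of 23 measured fetal and wall-stress genes, 16 rose and 1 fell in G-line HOM (19 and 1 adjusted over the list alone; median log2 fold change 0.99, camera adjusted p = 3.73e-11, and adjusted p = 0.358 with an estimated correlation). The member that fell was Myh7, the fetal-type myosin heavy chain gene of the mouse ventricle (-0.86 ± 0.17, adjusted p = 0.00281). The adult-type gene Myh6 fell as well (-0.54 ± 0.12, adjusted p = 0.00486). Nppa, the atrial natriuretic peptide gene, was at 6457 ± 1635 against 448.5 ± 646 CPM (3.85 ± 1.20, adjusted p = 0.0462), with WT replicate 2 at 1194 CPM and the other WT libraries at 64.2 and 87.0 CPM. The Nppa call was lost without WT replicate 1 (adjusted p = 0.0922), WT replicate 3 (0.107) or G-line HOM replicate 1 (0.0955), 2 (0.0888) or 3 (0.0631), and held without WT replicate 2 (0.00114). Acta1 (1.26, adjusted p = 0.110), Ttn (0.30, adjusted p = 0.0573), Camk2d (-0.02, adjusted p = 0.915) and Ldb3 (-0.13, adjusted p = 0.391) did not pass the test.

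Of 60 measured extracellular matrix genes, 44 rose in G-line HOM (52 adjusted over the list alone; median 1.66, camera adjusted p = 1.55e-21, and adjusted p = 0.358 with an estimated correlation). Among them were Ccn4 (2.45 ± 0.19), Sparc (1.68 ± 0.17, from 311 ± 16.6 to 996 ± 184 CPM) and Col8a1 (2.82 ± 0.28, from 43.4 ± 11.7 to 306 ± 53.5 CPM). Of 16 fibroblast markers, 9 rose (12 adjusted over the list alone; adjusted p = 1.13e-05, and adjusted p = 0.449 with an estimated correlation). The fibrillar collagen gene Col1a1 (1.75 ± 0.53, adjusted p = 0.0389) lost its call without WT replicate 1 (0.121), WT replicate 3 (0.123), G-line HOM replicate 1 (0.129) or G-line HOM replicate 2 (0.0652). Col3a1 (0.75, adjusted p = 0.0986) did not pass. Of 25 immediate-early genes, 13 rose (16 adjusted over the list alone; adjusted p = 4.57e-07, and adjusted p = 0.359 with an estimated correlation), including Fosl2 (1.53 ± 0.13) and Btg2 (1.58 ± 0.18).

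Of 43 fatty acid oxidation genes, 33 fell in G-line HOM (37 adjusted over the list alone; median -0.79, camera adjusted p = 5.23e-20, and adjusted p = 0.358 with an estimated correlation). Among them were the fatty acid transporter gene Cd36 (-0.82 ± 0.10, adjusted p = 7.91e-05) and the electron transfer gene Etfb (-1.09 ± 0.12, adjusted p = 2.74e-05). Of 79 nuclear-encoded respiratory chain genes, 43 fell (49 adjusted over the list alone; median -0.39, adjusted p = 1.37e-09, and adjusted p = 0.615 with an estimated correlation). Ndufa8 was at -0.57 ± 0.10 and Atp5g1 at -0.74 ± 0.14. Of 29 glycolysis genes, 7 rose and 12 fell (7 and 12 adjusted over the list alone), and the list was not called (median -0.21, adjusted p = 0.0955). The share of mitochondrial ribosomal RNA, which can vary with library preparation, was 10.8 to 13.5% in this group against 20.2 to 23.4% in WT. Whether it follows mitochondrial content was not tested. Of 15 cardiomyocyte markers, 9 fell (11 fell and 1 rose adjusted over the list alone; adjusted p = 7.19e-05, and adjusted p = 0.398 with an estimated correlation), such as Tnni3 (-1.07 ± 0.13), the cardiac troponin I gene, and Ckm (-1.69 ± 0.19), the muscle creatine kinase gene.

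Genes of excitation and calcium cycling moved both ways in G-line HOM. Of 32 ion channel and gap junction genes, 7 rose and 16 fell (7 and 16 adjusted over the list alone; median -0.46, camera adjusted p = 0.00904, and adjusted p = 0.398 with an estimated correlation). Kcnd2, a transient outward potassium channel gene, fell from 82.2 ± 1.74 to 5.06 ± 2.35 CPM (-4.02 ± 0.32, adjusted p = 2.74e-05). The potassium channel subunit gene Kcne1 (4.02 ± 0.37, adjusted p = 5.16e-05) and the T-type calcium channel gene Cacna1g (3.004 ± 0.30) rose. Of 34 calcium handling genes, 4 rose and 13 fell (4 and 14 adjusted over the list alone; adjusted p = 0.0429, and adjusted p = 0.545 with an estimated correlation). Atp2a2, the sarcoplasmic reticulum calcium pump gene, fell from 14090 ± 1032 to 5632 ± 1066 CPM (-1.32 ± 0.17, adjusted p = 0.000102). Ryr2, the cardiac ryanodine receptor gene (-0.28 ± 0.10, adjusted p = 0.0465), lost its call without WT replicate 1 (0.174), WT replicate 3 (0.151) or G-line HOM replicate 1 (0.0870), 2 (0.0767) or 3 (0.101).

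Of 35 integrated stress response genes, 18 rose and 5 fell in G-line HOM (21 and 5 adjusted over the list alone; camera adjusted p = 7.19e-05, and adjusted p = 0.358 with an estimated correlation). The transcription factor gene Atf4 was higher (1.32 ± 0.11, adjusted p = 4.08e-06) and the cationic amino acid transporter gene Slc7a1 lower (-1.66 ± 0.11, adjusted p = 1.30e-06). Of 29 RBM20 splicing targets, 7 rose and 8 fell (9 and 9 adjusted over the list alone). The list had a median of -0.10, a mean of 0.12 and a test toward higher values that did not pass (adjusted p = 0.665). Gene totals do not measure splicing. Of 26 sarcomere genes, 7 rose and 7 fell (9 and 10 adjusted over the list alone; adjusted p = 0.665). Other lists were called as well, with counts adjusted over the list alone in parentheses. Of 44 ribosomal protein genes 9 (9) rose and 1 (1) fell (adjusted p = 0.0266, and adjusted p = 0.895 with an estimated correlation). Of 27 p53 and cell death genes 8 (9) rose and 1 (1) fell (adjusted p = 0.00521, and adjusted p = 0.358 with an estimated correlation). Of 16 smooth muscle markers 7 (7) fell and 1 (1) rose (adjusted p = 0.0107, and adjusted p = 0.449 with an estimated correlation). Of 9 erythroid genes 4 (6) rose (adjusted p = 0.0105, and adjusted p = 0.806 with an estimated correlation), beside the Hbb-bt values of G-line HOM replicates 1 and 2. Among 7 skeletal muscle markers 3 (3), Casq1, Myl1 and Tnnt3, rose and 1 (1), Ckm, which is also among the cardiomyocyte markers, fell (adjusted p = 0.0230, and adjusted p = 0.358 with an estimated correlation).

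In all, 4640 of 17588 tested genes differed between G-line HOM and WT, 2306 higher and 2334 lower, and 1633 of them by over 2-fold. The count was 2226 with the 2 shared libraries left out and 1151 with them counted as A-line HOM. Of the genes named here Chodl, Grin2a, Ereg, Myh6, Ryr2 and Col1a1 lost their call when the shared libraries were left out (adjusted p = 0.0519 to 0.129). Of 38 tested lists 15 were called by camera with its preset correlation and 0 with an estimated correlation. The fry test, of whether a list's genes move on balance one way without comparing them with other genes, also called 15.

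**Figure D1:**
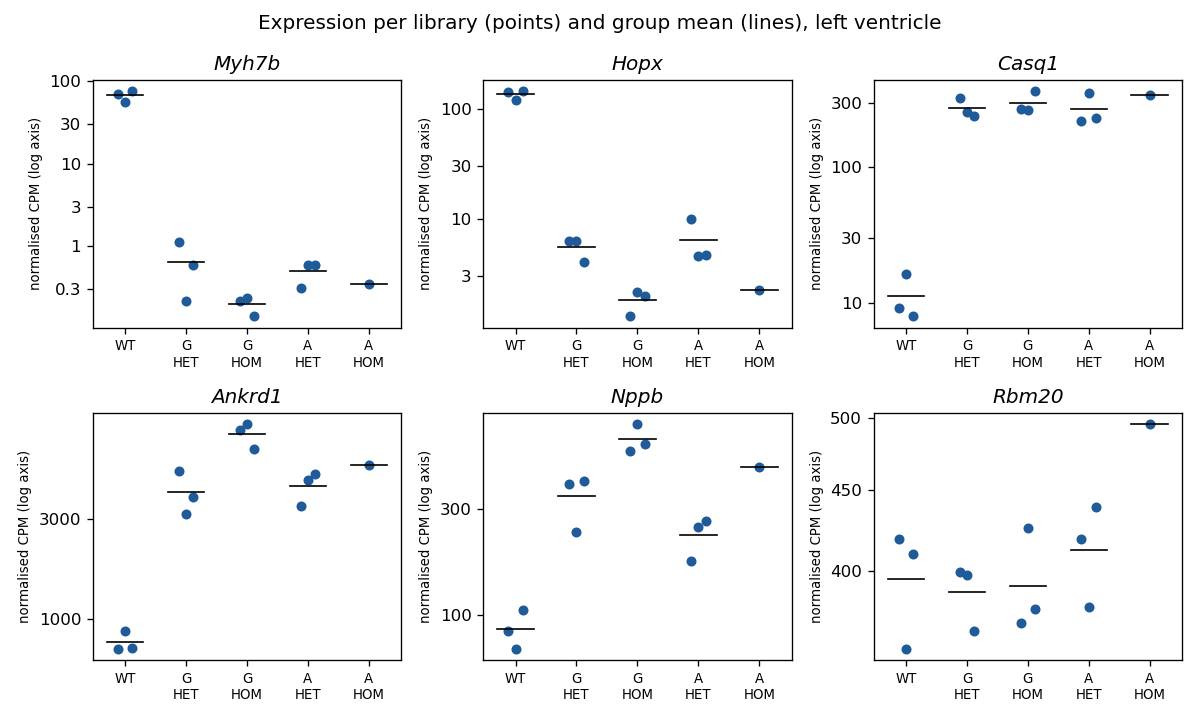
Normalised CPM (log axis) of Myh7b, Hopx, Casq1, Ankrd1, Nppb and Rbm20 in each of the 13 distinct libraries by group; points are libraries and lines are group means. Myh7b averaged 66.9 CPM in WT and 0.199 CPM in G-line HOM, Casq1 11.2 and 298.5 CPM, and Rbm20 395 and 391 CPM.

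The A-line HOM library was compared with WT to ask what the S637A allele does in both copies. Myh7b (0.343 against 66.9 ± 10.3 CPM, n = 1 and 3; -7.58 ± 0.59, adjusted p = 4.48e-05) was again far lower. So were Hopx (2.23 against 138 ± 13.6 CPM; -5.95 ± 0.55, adjusted p = 0.000329) and Aqp4 (0.171 against 9.70 ± 1.96 CPM; -5.78 ± 0.76, adjusted p = 0.000855). Acsm5, which encodes a medium-chain acyl-CoA synthetase, was at least 21.7-fold lower and Rgs13 at least 20.7-fold lower, neither having a count in the A-line HOM library (floor of 3 counts). Strit1 was at 0.0571 against 5.59 ± 0.951 CPM. Casq1 rose to 341 CPM (4.93 ± 0.36, adjusted p = 9.78e-05), Ankrd1 by 2.82 ± 0.23 (adjusted p = 4.48e-05) and Nppb by 2.40 ± 0.29 (adjusted p = 0.00132). The stress-induced transcription factor gene Atf3 was at 115 against 2.57 ± 1.14 CPM (5.47 ± 0.54, adjusted p = 0.000855) and Egr3 at 7.60 against 0.314 CPM (4.58 ± 0.54, adjusted p = 0.000383).

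Of 25 immediate-early genes, 14 rose in A-line HOM (18 adjusted over the list alone; median 1.98, camera adjusted p = 1.56e-41). This call held with an estimated correlation (adjusted p = 0.0229). Examples were Btg2 (2.77 ± 0.23), Fosl2 (2.02 ± 0.17), Jun (1.94 ± 0.22) and Ccn1 (1.98 ± 0.17). All these values come from 1 A-line HOM library, so the state of that sample cannot be told apart from an effect of the allele. Of 35 integrated stress response genes, 10 rose and 2 fell (17 and 2 adjusted over the list alone; camera adjusted p = 8.51e-10, and adjusted p = 0.110 with an estimated correlation). Atf4 was at 1.21 ± 0.14 and Slc7a1 at -1.66 ± 0.17. Of 23 fetal and wall-stress genes, 5 rose (12 adjusted over the list alone; adjusted p = 8.25e-12, and adjusted p = 0.224 with an estimated correlation). Of 43 fatty acid oxidation genes, 6 fell (22 fell and 1 rose adjusted over the list alone; adjusted p = 1.44e-08). Among 45 interferon response genes 6 fell (14 adjusted over the list alone; median -0.61, adjusted p = 3.44e-11). Both lists had adjusted p = 0.519 with an estimated correlation. Beside the interferon genes, macrophage markers were called lower as a list (median -0.38, adjusted p = 0.0344, and adjusted p = 0.682 with an estimated correlation), with 0 of 18 called by edgeR (0 adjusted over the list alone). The interferon members Irgm2 (-0.96), Ifit3b (-1.43) and Gbp7 (-0.91) and the fatty acid gene Acot1 (-2.02) lay slightly above 0 when the shared libraries were counted as A-line HOM. The last 3 lost their calls without WT replicate 3 (adjusted p = 0.0538, 0.0769 and 0.0654). Of 60 matrix genes, 4 rose (4 adjusted over the list alone; adjusted p = 8.38e-06, and adjusted p = 0.682 with an estimated correlation), among them Ccn4 (1.87 ± 0.25). Fibroblast markers (median 0.48, adjusted p = 0.0245) and cardiomyocyte markers (median -0.26, adjusted p = 0.0259) were called as lists, with 0 of 16 and 0 of 15 called by edgeR (0 and 0 adjusted over the list alone). Smooth muscle and pericyte markers (0 of 16 called, median -0.46, adjusted p = 0.0362) and ribosomal protein genes (0 of 44, median 0.17, adjusted p = 0.004155) were called as well (0 and 0 adjusted over the list alone by edgeR). Each of these 4 lists had adjusted p = 0.682 with an estimated correlation. Of 7 skeletal muscle markers 1, Casq1, rose (3 rose and 1 fell adjusted over the list alone; median 1.52, adjusted p = 0.0001505, and adjusted p = 0.110 with an estimated correlation).

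Of the textbook remodelling genes, Atp2a2 fell in A-line HOM (-0.96 ± 0.25, adjusted p = 0.0450), a call lost without WT replicate 1 (0.101), 2 (0.0537) or 3 (0.108). Nppa (3.27 ± 1.37, adjusted p = 0.247), Myh7 (-0.34, adjusted p = 0.518), Myh6 (-0.24, adjusted p = 0.518), Acta1 (0.87, adjusted p = 0.569) and Ttn (0.36, adjusted p = 0.210) did not pass. Nor did Camk2d (0.12, adjusted p = 0.702), Ryr2 (-0.26, adjusted p = 0.357), Ldb3 (0.00, adjusted p = 0.996), Col1a1 (0.64, adjusted p = 0.700), Col3a1 (-0.14, adjusted p = 0.912) and Postn (0.48, adjusted p = 0.777). Nppa stood at 4327 CPM in the A-line HOM library against 64.2, 1194 and 87.0 CPM in WT replicates 1, 2 and 3. WT replicate 2 held atrial transcripts, so the missing call does not show an unchanged Nppa level. In all, 823 genes differed, 496 higher and 327 lower, and 3309 had an unadjusted p under 0.05. The count was 102 with the shared libraries left out, 0 by edgeR with them counted as A-line HOM (569 at an unadjusted p under 0.05), 398 without WT replicate 3 and 435 without WT replicate 1. Of the genes with the largest changes, Kctd16, Tent5b, Mgat5b, Egr2, Nr4a3, Slc26a4, Cfap61, Cngb3 and Pm20d1 lost their calls with the shared libraries left out (adjusted p = 0.0571 to 0.15). So did Atp2a2 and the 4 interferon and fatty acid genes named above. Mgat5b, Kctd16, Cngb3 and Pm20d1 also lost theirs without WT replicate 1 (adjusted p = 0.0520 to 0.0732).

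Heterozygous G-line hearts were compared with WT to ask whether a single mutated copy is enough. Myh7b (0.646 ± 0.462 CPM, SD, n = 3; -6.65 ± 0.31, adjusted p = 4.65e-07), Hopx (5.54 ± 1.30 CPM; -4.64 ± 0.29, adjusted p = 1.88e-05) and Aqp4 (0.292 CPM; -5.00 ± 0.41, adjusted p = 1.44e-05) were far below WT. Strit1 had no count, at least 143.2-fold lower against a floor of 3 counts over the group. Rp1, Lincred1, Acsm5, Pde11a and Rhd fell by log2 fold changes of -4.80, -4.54, -4.31, -4.18 and -3.93. Casq1 rose to 273 ± 45.5 CPM (4.61 ± 0.32, adjusted p = 4.79e-05), Ankrd1 to 4057 ± 988 CPM (2.39 ± 0.19, adjusted p = 1.44e-05) and Nppb to 341 ± 91.3 CPM (1.97 ± 0.23, adjusted p = 0.000670). Kcnd2 (-2.36 ± 0.29) and Gja1, the gap junction gene of ventricular muscle (-0.93 ± 0.12, adjusted p = 0.000381), fell.

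Of 7 skeletal muscle markers, 3, Casq1, Myl1 and Tnni2, rose in G-line HET (4 adjusted over the list alone; median 2.63, camera adjusted p = 3.00e-09). This call held with an estimated correlation (adjusted p = 0.0244). Myl1, a fast-type myosin light chain gene, rose to 237 ± 21.6 CPM from 38.2 ± 13.6 (2.63 ± 0.32, adjusted p = 0.00115). Tnni2, the fast-type troponin I gene, rose to 29.4 ± 6.86 CPM from 1.19 ± 0.580 (4.61 ± 0.60, adjusted p = 0.00256). Mybpc2, the fast-type myosin-binding protein C gene, rose to 195 ± 40.0 CPM from 22.8 ± 10.4 (3.09 ± 0.39). Of 60 matrix genes, 14 rose (27 adjusted over the list alone; median 0.89, adjusted p = 7.52e-19, and adjusted p = 0.533 with an estimated correlation), such as Ccn4 (1.59 ± 0.19) and Col8a1 (2.12 ± 0.27). With them, 4 of 16 fibroblast markers rose (7 adjusted over the list alone; median 0.62, adjusted p = 4.42e-06, and adjusted p = 0.656 with an estimated correlation). Of 23 fetal and wall-stress genes, 7 rose and 1, Myh7 (-1.15 ± 0.17), fell (12 and 1 adjusted over the list alone; adjusted p = 4.48e-07). Among 25 immediate-early genes 7 rose (10 adjusted over the list alone; adjusted p = 1.18e-08). Both lists had adjusted p = 0.533 with an estimated correlation. Of 43 fatty acid oxidation genes, 6 fell and 1 rose (9 and 1 adjusted over the list alone; adjusted p = 8.42e-05, and adjusted p = 0.745 with an estimated correlation). Integrated stress response genes were called higher, with 5 of 35 that rose and 3 that fell (9 and 3 adjusted over the list alone; adjusted p = 0.0210, and adjusted p = 0.745 with an estimated correlation). So were p53 and cell death genes, of which 5 of 27 rose (5 adjusted over the list alone; adjusted p = 0.00707, and adjusted p = 0.435 with an estimated correlation). Lymphocyte markers were called lower, and 1 of 8, Cd79b, fell (3 adjusted over the list alone; median -1.003, adjusted p = 0.00819, and adjusted p = 0.562 with an estimated correlation). Among 29 RBM20 splicing targets 6 rose and 1 fell (9 and 1 adjusted over the list alone), and the list was not called (adjusted p = 0.213).

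In all, 1322 genes differed between G-line HET and WT, 699 higher and 623 lower. The count was 236 with the shared libraries left out, 5 with them counted as A-line HOM, 515 without G-line HET replicate 1, 543 without WT replicate 1, 599 without WT replicate 3 and 740 without G-line HET replicate 3. Of the genes with the largest rises, Tnni2, Nos1, Tent5b, Cilp and Rasgef1a lost their calls with the shared libraries left out (adjusted p = 0.0598 to 0.346). All of these but Tnni2 also lost them without WT replicate 1 (0.0585 to 0.158) or WT replicate 3 (0.0552 to 0.141).

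Heterozygous A-line hearts, compared with WT for the same question, showed Myh7b at 0.494 ± 0.155 CPM (SD, n = 3; -7.02 ± 0.34, adjusted p = 6.27e-07), Hopx at 6.37 ± 3.08 CPM (-4.47 ± 0.30, adjusted p = 3.48e-05) and Aqp4 at 0.537 CPM (-4.24 ± 0.41, adjusted p = 4.66e-05). Strit1 had no count and was at least 90.5-fold lower against a floor of 3 counts over the group. Rgs13 stood at 0.0194 against 3.55 ± 0.440 CPM. Casq1 rose to 268 ± 72.1 CPM (4.58 ± 0.32, adjusted p = 4.66e-05) and Ankrd1 to 4345 ± 784 CPM (2.49 ± 0.19, adjusted p = 1.43e-05). The T-type calcium channel gene Cacna1h rose to 37.5 ± 5.68 from 6.42 ± 3.69 CPM (2.53 ± 0.32, adjusted p = 0.00142). Nppb was at 229 ± 48.1 CPM (1.40 ± 0.23, adjusted p = 0.00449), and its call was lost without the libraries with atrial transcripts (adjusted p = 0.0701). Bcl2l11, the gene of a pro-apoptotic BCL2 relative, rose by 1.65 ± 0.16 (adjusted p = 4.66e-05).

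In A-line HET 4 of 7 skeletal muscle markers rose, Casq1, Myl1, Tnni2 and Tnnt3 (4 rose and 1 fell adjusted over the list alone; median 2.13, camera adjusted p = 3.73e-09). The call held with an estimated correlation (adjusted p = 0.0214). Tnni2 rose to 27.9 ± 7.06 CPM (4.53 ± 0.61, adjusted p = 0.00266) and Mybpc2 to 252 ± 102 CPM (3.46 ± 0.40, adjusted p = 0.00138). Of 43 fatty acid oxidation genes, 15 fell (24 fell and 1 rose adjusted over the list alone; median -0.42, adjusted p = 1.18e-10, and adjusted p = 0.594 with an estimated correlation), including Cd36, from 1895 ± 177 to 1222 ± 111 CPM (-0.63 ± 0.10, adjusted p = 0.00215). Of 15 cardiomyocyte markers, 2 fell (3 adjusted over the list alone; adjusted p = 0.00213, and adjusted p = 0.594 with an estimated correlation). Of 35 integrated stress response genes, 11 rose and 2 fell (16 and 3 adjusted over the list alone; adjusted p = 0.00110, and adjusted p = 0.594 with an estimated correlation), with Atf4 at 0.77 ± 0.11 and Slc7a1 at -1.75 ± 0.11. Of 60 matrix genes, 7 rose (7 adjusted over the list alone; adjusted p = 6.90e-11), among them Ccn4 (1.98 ± 0.19). With them, 1 of 16 fibroblast markers rose (6 adjusted over the list alone; median 0.76, adjusted p = 4.80e-06). Both lists had adjusted p = 0.594 with an estimated correlation. Of 25 immediate-early genes, 6 rose (8 adjusted over the list alone; adjusted p = 2.81e-06, and adjusted p = 0.594 with an estimated correlation). Fetal and wall-stress genes were called higher, with 6 of 23 that rose and 1, Myh7 (-0.92 ± 0.17), that fell (6 and 1 adjusted over the list alone; adjusted p = 0.000125, and adjusted p = 0.594 with an estimated correlation). Respiratory chain genes were called lower (median -0.12, adjusted p = 0.0489), with 0 of 79 called by edgeR (0 adjusted over the list alone). Ribosomal protein genes were called higher (median 0.13, adjusted p = 0.0436), although the 1 of 44 that passed the test, Rps2 (-0.36), fell (0 adjusted over the list alone by edgeR). The last 2 lists had adjusted p = 0.897 with an estimated correlation. Among 29 RBM20 splicing targets 4 rose and 3 fell (5 and 5 adjusted over the list alone; adjusted p = 0.847).

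In all, 1400 genes differed between A-line HET and WT, 701 higher and 699 lower. The count was 165 with the shared libraries left out, 0 by edgeR with them counted as A-line HOM (2118 at an unadjusted p under 0.05), 622 without WT replicate 3 and 652 without WT replicate 1. It was 704 without A-line HET replicate 3, 707 without A-line HET replicate 2, 2038 without A-line HET replicate 1, 651 without the libraries with atrial transcripts and 834 without those with shifted clock genes. Of the genes with the largest rises, Mylk2, Tnni2, Tnnt3, Grin2a, Nos1, Kctd16, Rasgef1a and Slc26a4 lost their calls with the shared libraries left out (adjusted p = 0.0634 to 0.348), as did Nppb (0.0781). Tnnt3, Grin2a, Nos1 and Kctd16 also lost theirs without WT replicate 1 (0.0514 to 0.149).

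G-line HOM was compared with G-line HET to ask what the second mutated copy adds. Neither group holds a shared library, but the spread used in the test was estimated from all 13 libraries, the shared ones included. Genes of mitochondrial energy supply were lower in G-line HOM. Of 79 nuclear-encoded respiratory chain genes, 43 fell (64 adjusted over the list alone; median -0.40, camera adjusted p = 2.84e-21, and adjusted p = 0.444 with an estimated correlation). Among them were Ndufs7, from 112 ± 14.98 to 56.5 ± 9.15 CPM (SD, n = 3; -0.99 ± 0.14, adjusted p = 0.00156) and Ndufa8 (-0.72 ± 0.10). Of 43 fatty acid oxidation genes, 26 fell (32 adjusted over the list alone; adjusted p = 4.77e-17, and adjusted p = 0.334 with an estimated correlation). They included Hadh, from 389 ± 9.11 to 175 ± 39.7 CPM (-1.15 ± 0.17, adjusted p = 0.00189), and Plin5, a lipid droplet gene (-0.90 ± 0.12). The share of mitochondrial ribosomal RNA, which can vary with library preparation, was 10.8 to 13.5% in G-line HOM and 15.4 to 16.7% in G-line HET. Of 29 glycolysis genes, 12 fell and 1 rose (14 and 1 adjusted over the list alone; adjusted p = 5.70e-06), such as the muscle glycogen phosphorylase gene Pygm (-0.71 ± 0.10). Of 15 cardiomyocyte markers, 10 fell (10 fell and 1 rose adjusted over the list alone; adjusted p = 6.75e-07), such as Tnni3 (-0.91 ± 0.13). Both lists had adjusted p = 0.444 with an estimated correlation.

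Of 32 ion channel and gap junction genes, 15 fell and 5 rose in G-line HOM against G-line HET (22 and 5 adjusted over the list alone; camera adjusted p = 1.21e-06, and adjusted p = 0.334 with an estimated correlation). The pacemaker channel gene Hcn4 (-1.59 ± 0.24) and the potassium channel gene Kcnh2 (-0.94 ± 0.15) fell and Kcne1 (2.56 ± 0.33) rose. Scn4b was at 0.308 ± 0.258 against 14.4 ± 2.00 CPM (-5.51 ± 0.90, adjusted p = 0.00666). Acsl6 was at 0.485 against 12.2 ± 0.671 CPM (-4.69 ± 0.64) and the endothelin gene Edn3 at 0.162 against 2.701 ± 0.822 CPM (-4.11 ± 0.52). Ryr1, the skeletal ryanodine receptor gene, was at 0.0732 against 9.02 ± 4.74 CPM (-6.94 ± 1.60, adjusted p = 0.0230), a call lost without any library of G-line HOM or G-line HET replicates 1 and 2 (adjusted p = 0.0527 to 0.0861). Tnni2, high in G-line HET, was lower in G-line HOM, at 2.57 ± 2.07 CPM (-3.52 ± 0.55, adjusted p = 0.00512). Tnni1, the slow-type troponin I gene, rose (3.79 ± 0.70). Atp2a2 (-0.77 ± 0.17, adjusted p = 0.0104) fell and Ankrd1 (0.93 ± 0.18, adjusted p = 0.00592) rose further from their WT levels. Of 45 interferon response genes, 9 rose (9 adjusted over the list alone; adjusted p = 0.000114), such as Ifit2 (0.93 ± 0.12). Of 60 matrix genes, 8 rose and 1 fell (9 and 1 adjusted over the list alone; adjusted p = 1.21e-06). Both had adjusted p = 0.579 with an estimated correlation. Against WT the interferon list was called lower in G-line HET (1 rose and 1 fell, 0 and 1 adjusted over the list alone; median -0.18, adjusted p = 0.0418, and adjusted p = 0.875 with an estimated correlation). It was not called in G-line HOM against WT (6 rose, 4 adjusted over the list alone, adjusted p = 0.2999). Between G-line HOM and G-line HET, 8 of 23 fetal and wall-stress genes rose (8 rose and 1 fell adjusted over the list alone; adjusted p = 1.44e-05) and 7 of 35 integrated stress response genes rose and 1 fell (14 and 2 adjusted over the list alone; adjusted p = 0.00344). Calcium handling genes were called lower, with 9 of 34 that fell (10 adjusted over the list alone; adjusted p = 0.00795), as were skeletal muscle markers, with 2 of 7, Tnni2 and Ckm, that fell (2 adjusted over the list alone; adjusted p = 0.0400). These 4 lists had adjusted p = 0.444 with an estimated correlation. Of 26 sarcomere genes 9 fell and 1 rose (10 and 2 adjusted over the list alone; adjusted p = 0.0143, and adjusted p = 0.579 with an estimated correlation). Of 44 ribosomal protein genes 9 rose and 1 fell (11 and 1 adjusted over the list alone; adjusted p = 0.0280), and of 9 erythroid genes 1 rose (0 adjusted over the list alone by edgeR, adjusted p = 0.0497). The last 2 lists had adjusted p = 0.688 with an estimated correlation.

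In all, 2575 genes differed between G-line HOM and G-line HET, 1094 higher and 1481 lower. The count was 1168 without G-line HOM replicate 2, 1320 without G-line HET replicate 1 and 1325 without G-line HET replicate 2. It was 1428 without G-line HOM replicate 1, 1468 without G-line HET replicate 3, 1558 without the libraries with atrial transcripts and 1531 without those with shifted clock genes.

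**Figure D2:**
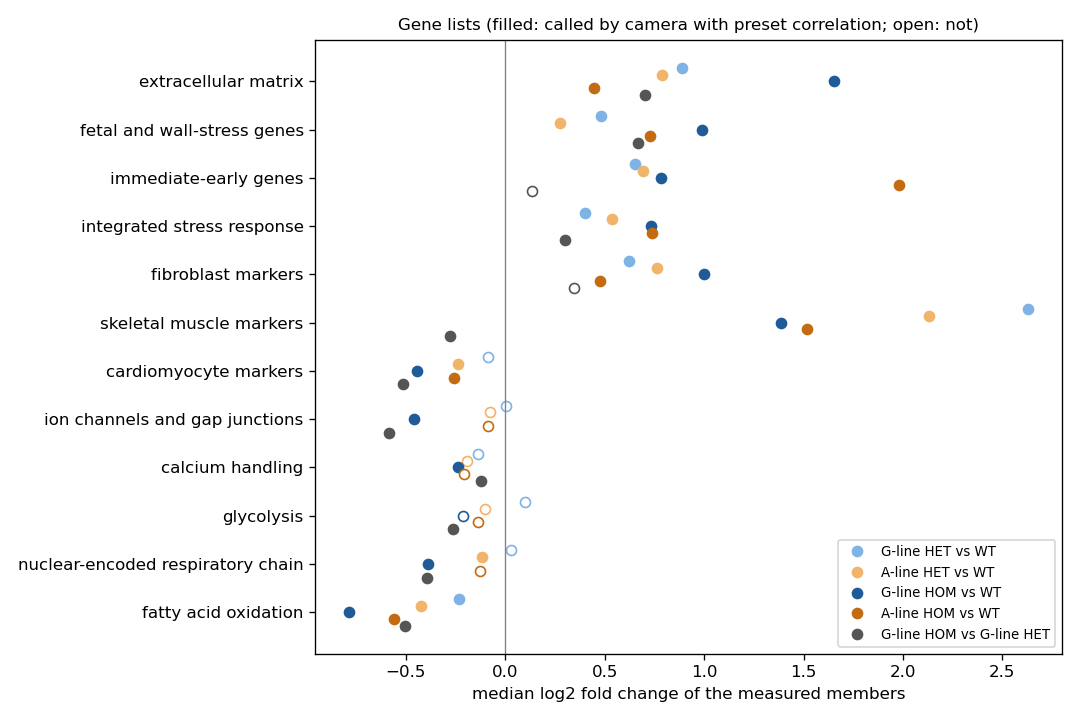
Median log2 fold change (horizontal axis) of 12 gene lists in 5 comparisons (G-line HET, A-line HET, G-line HOM and A-line HOM against WT, and G-line HOM against G-line HET); a filled point is a list called by camera with its preset correlation and an open point one not called. Fatty acid oxidation genes had a median of -0.79 in G-line HOM and matrix genes one of 1.66.

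The A-line HOM library was compared with A-line HET to ask the same of the S637A allele. Since it is 1 library, its state cannot be told apart from an effect of the allele. Of the immediate-early genes, Btg2 stood at 205.5 CPM against a mean of 61.1 CPM (1.75 ± 0.23, adjusted p = 0.0278). Ccn1, a matricellular gene of that response, stood at 103 against 41.9 CPM (1.29 ± 0.18, adjusted p = 0.0278). Of 25 such genes 2 rose (16 adjusted over the list alone), and the list was called with the preset (adjusted p = 1.34e-58) and with an estimated correlation (adjusted p = 0.00754). Fetal and wall-stress genes were called higher, with 1 of 23, Ccn1, that rose (1 adjusted over the list alone; median 0.33, adjusted p = 2.48e-08, and adjusted p = 0.3004 with an estimated correlation). The preset also called 8 lists in which edgeR called 0 genes. Higher were integrated stress response genes (median 0.27, adjusted p = 1.64e-07), splicing factors and SR kinases (0.12, adjusted p = 4.84e-05) and heat shock genes (0.15, adjusted p = 0.0001255). RNA granule (0.08, adjusted p = 0.00763), sarcomere (0.07, adjusted p = 0.0288) and antioxidant genes (0.10, adjusted p = 0.0288) were higher too. Interferon response genes (-0.51, adjusted p = 5.33e-20) and skeletal muscle markers (-1.32, adjusted p = 0.0294) were lower. Adjusted over the list alone, 1 stress response and 1 heat shock gene were higher, 4 interferon genes lower and 0 genes of the other 5 lists called by edgeR. With an estimated correlation these 8 lists had adjusted p = 0.220 to 0.788. The other called genes were Ifrd1 (0.83 ± 0.12, adjusted p = 0.0330) and Gm35261 (1.81 ± 0.25), the latter named after its values were seen. In all, 4 genes rose (n = 1 and 3), with 813 at an unadjusted p under 0.05 and 25 by DESeq2. The edgeR count was 0 with the shared libraries left out (670 at an unadjusted p under 0.05), 0 without A-line HET replicate 2 (816) and 1 without A-line HET replicate 1.

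The homozygous lines were compared with each other to ask whether the alleles differ. Cux2, a homeobox gene (1.43 ± 0.20), Lama5, a laminin chain gene (1.19 ± 0.17), and Slc38a3, a glutamine transporter gene (1.13 ± 0.16), were higher in the A-line HOM library than in G-line HOM (each adjusted p = 0.0243). Gm29901, Gm35261, Gm35750 and Gm52092, named after their values were seen, completed the 7 calls, all higher in A-line HOM, with 2070 genes at an unadjusted p under 0.05 and 185 called by DESeq2. Interferon response genes had a median of -0.65 (0 of 45 called, 30 lower adjusted over the list alone; camera adjusted p = 7.03e-26, and adjusted p = 0.205 with an estimated correlation). Immediate-early genes had one of 1.19 (0 of 25 called, 16 higher adjusted over the list alone; adjusted p = 5.71e-20, and adjusted p = 0.199 with an estimated correlation). Camera called 12 further lists in which edgeR called 0 genes. Respiratory chain (median 0.27, adjusted p = 6.89e-12), fatty acid oxidation (0.36, adjusted p = 4.23e-09) and ion channel genes (0.35, adjusted p = 3.37e-06) were higher as lists in A-line HOM, as were heat shock genes (0.17, adjusted p = 0.000702) and cardiomyocyte markers (0.24, adjusted p = 0.00586). Adjusted over the list alone, 1, 5, 4, 1 and 0 of their genes were higher by edgeR. Lower were matrix genes (-1.03, adjusted p = 4.34e-17), erythroid genes (-1.575, adjusted p = 3.87e-06), unfolded protein response genes (-0.23, adjusted p = 0.000166) and fibroblast markers (-0.44, adjusted p = 0.000898). Cell cycle (-0.28, adjusted p = 0.00686), p53 and cell death (-0.28, adjusted p = 0.0161) and cytokine genes (-0.37, adjusted p = 0.0284) were lower too. Adjusted over the list alone, 1 matrix gene and 2 erythroid genes were lower and 0 genes of the other 5 lists by edgeR. With an estimated correlation these 12 lists had adjusted p = 0.205 to 0.586. The edgeR count was 0 with the shared libraries left out (1802 at an unadjusted p under 0.05) or without G-line HOM replicate 2 (1675) and 153 without G-line HOM replicate 3. It was 1 without G-line HOM replicate 1, and 2 without the libraries with atrial transcripts or those with shifted clock genes.

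The heterozygous lines differed in few genes. Bcl2l11 was higher in A-line HET than in G-line HET, at 49.4 against 23.1 CPM (1.10 ± 0.15, n = 3 each, adjusted p = 0.0365). Edn3 (-3.56 ± 0.52, adjusted p = 0.0393), the zinc transporter gene Slc39a14 (-0.74 ± 0.11, adjusted p = 0.0398) and the small heat shock protein gene Hspb6 (-0.66 ± 0.10, adjusted p = 0.0398) were lower. LOC118568781, named after its values were seen, was higher (4.25 ± 0.49). Camera called 12 lists, 11 of them lower in A-line HET. These were cell cycle (median -0.52, adjusted p = 3.02e-07), glycolysis (-0.22, adjusted p = 7.01e-08), respiratory chain (-0.13, adjusted p = 1.49e-06), sarcomere (-0.165, adjusted p = 5.67e-06) and heat shock genes (-0.15, adjusted p = 1.05e-05). With them came cardiomyocyte markers (-0.22, adjusted p = 0.000172) and fatty acid oxidation (-0.18, adjusted p = 0.00298), matrix (-0.26, adjusted p = 0.00441), antioxidant (-0.06, adjusted p = 0.0251) and autophagy and atrophy genes (-0.08, adjusted p = 0.0322). Calcium handling genes had a median of -0.10, a mean of 0.08 and a test toward lower values (adjusted p = 0.0142). Lymphocyte markers were higher (1.20, adjusted p = 0.000517). Hspb6 was the only called member of these lists. Adjusted over the list alone, 4 glycolysis, 5 sarcomere, 2 heat shock, 2 cardiomyocyte, 2 fatty acid oxidation and 3 calcium handling genes were lower. By the same adjustment 3 lymphocyte markers and 1 fatty acid oxidation gene were higher, and edgeR called 0 genes of the other 5 lists. With an estimated correlation the 12 lists had adjusted p = 0.4915 to 0.914. The 5 calls of single genes stood beside 2331 genes at an unadjusted p under 0.05 and 252 by DESeq2. The edgeR count was 0 without A-line HET replicate 2, G-line HET replicate 1 or G-line HET replicate 3 (1412 to 1902 at an unadjusted p under 0.05), 1 without A-line HET replicate 3, 8 without G-line HET replicate 2 and 607 without A-line HET replicate 1. It was 3 with the shared libraries left out (2 of them among the 5), 3 without the libraries with atrial transcripts (1 among the 5) and 0 without those with shifted clock genes (1821).

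Whether the second mutated copy had another effect in the A-line than in the G-line was tested as a difference of differences. Its A-line HOM values are those of 1 library, whose spread was assumed to be like that of the other groups. Slc38a3 averaged 63.1 CPM in G-line HET and 31.3 in G-line HOM, and 46.3 in A-line HET and 68.4 in A-line HOM (1.58 ± 0.20, adjusted p = 0.0239). Lama5 averaged 122 and 50.4 CPM in G-line HET and HOM and 100.2 and 115 in the A-line (1.47 ± 0.22, adjusted p = 0.0462). Cux2 averaged 14.1 and 5.91 CPM and 11.5 and 15.8 CPM (1.72 ± 0.25, adjusted p = 0.0462). These 3 genes were the only calls by edgeR in this test, with 2439 at an unadjusted p under 0.05 and 261 by DESeq2. The count was 516 without A-line HET replicate 1, 52 without G-line HOM replicate 3, and 0 without A-line HET replicate 2 or 3, G-line HET replicate 1 or 3 or G-line HOM replicate 2, with the shared libraries left out or without those with atrial transcripts (1722 to 2241 at an unadjusted p under 0.05). It was 1 without the libraries with shifted clock genes.

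The effects of the lines against WT were positively correlated across genes. Across 17588 genes, which are not independent replicates, the log2 fold changes of G-line HOM and A-line HOM against WT had a Pearson r of 0.668 (Spearman rho 0.608) and a covariance of 0.534. Those of G-line HET and A-line HET had an r of 0.686 (rho 0.594) and a covariance of 0.278. Both lines share the WT libraries. Unchanged groups compared with a shared, simulated WT gave a mean r of 0.301 and covariance of 0.0586 for HOM over 20 simulations. For HET these were 0.485 and 0.0600. The simulations drew all libraries, WT included, around 1 mean per gene, so what is peculiar to the real WT libraries is not in these values. The covariances exceeded the simulated ones by 0.475 and 0.218. Of the genes called higher, 441 were shared by G-line HOM and A-line HOM, against 65.0 for independent lists and 0 in the simulations. Of those called lower 293 were shared, against 43.4 and 0.05. For HET, 395 higher and 325 lower genes were shared, against 27.9 and 24.8 for independent lists and 0 and 0 in the simulations. Unchanged groups hold hardly any calls to share, so the simulated overlaps were fixed in advance. The values for independent lists leave out that both lists use the same WT libraries. Neither tests whether the overlaps exceed what the shared WT gives. The 3 WT libraries cannot be split into 2 parts of 2 libraries, so part of the excess may come from the shared controls. The HOM minus HET effects of the lines, which share no library, had an r of -0.0301 (rho 0.0292) against a simulated 0.00267, and its sign turned with the shared libraries left out (0.00692).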

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

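Of the tests in this part, those without the shared libraries, without the libraries with atrial transcripts or without those with shifted clock genes were chosen after the result was seen.

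The heterozygous lines differed from each other in 5 genes by a test of the difference itself, as did the homozygous lines in 7 and the HOM minus HET effects in 3. A-line HET differed from G-line HET in Bcl2l11 (log2 fold change 1.10, adjusted p = 0.0365), Edn3 (-3.56, adjusted p = 0.0393), Hspb6 (-0.66, adjusted p = 0.0398), Slc39a14 (-0.74, adjusted p = 0.0398) and LOC118568781 (4.25, adjusted p = 0.00746). The 10 splits of these 6 libraries are too few for a share under 0.05. The real split gave 5 genes and the highest other 1, so that 1 split of all gave as many. With the shared libraries left out 3 genes were called, 2 of them among these 5, and without the libraries with atrial transcripts 3, of which 1 was among the 5. Without those with shifted clock genes edgeR called 0 (1821 at an unadjusted p under 0.05; 252 by DESeq2 on all 13 libraries).

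A difference between the homozygous lines was found in Cux2 (1.43), Lama5 (1.19) and Slc38a3 (1.13), each with adjusted p = 0.0243 (1 A-line HOM library against 3). The effect of the second mutated copy differed between the lines in the same genes, Cux2 (1.72, adjusted p = 0.0462), Lama5 (1.47, adjusted p = 0.0462) and Slc38a3 (1.58, adjusted p = 0.0239). Both tests use the same A-line HOM library and the same G-line HOM libraries, so this recurrence is partly built in. In either test 0 of these 3 genes kept the call in every alternative, which was fixed in advance by alternatives that left no call by edgeR. With the shared libraries left out edgeR called 0 genes in both tests (1802 and 2068 at an unadjusted p under 0.05), and DESeq2 called 185 and 261 with them.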

How the results depend on the processing

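The tests with the shared pair as A-line HOM, left out or in both groups, and those without the libraries with atrial transcripts or shifted clock genes, were chosen after the result was seen; the others were planned. Every comparison with WT or A-line HOM rests on which name the shared libraries carry, and A-line HOM rests on 1 library. The sex covariate was not run because 13 of 13 libraries looked alike in sex, and symbols missing from a table did not arise. Scaling choices moved the median of all genes by less than 0.1 log2. Where no reason is given below, the cause was not tested.

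Gene counts are given in the order G-line HOM, A-line HOM, G-line HET and A-line HET against WT (4640, 823, 1322 and 1400), G-line HOM against HET (2575), A-line HOM against HET (4), HOM between lines (7), HET between lines (5) and the difference of differences (3). Counts that moved by over 1.5 times follow. With the pair as A-line HOM, which leaves 1 WT library, they were 1151, 0, 5, 0, 1251, 0, 1701, 1 and 446. Each 0 was by edgeR, with 569, 2118 and 1284 genes at an unadjusted p under 0.05. With the pair left out, which leaves 1 library in both groups, they were 2226, 102, 236 and 165 against WT, then 0 for A-line HOM against HET (670 unadjusted), 0 for HOM between lines (1802), 3 for HET between lines and 0 for the difference of differences (2068). With all 15 columns, where the same counts stand in both groups, A-line HOM against WT gave 0 by edgeR (81 unadjusted), G-line HET 439, A-line HET 0 (3556), A-line HOM against HET 0 (1568), HOM between lines 2285, HET between lines 1 and the difference of differences 1336.

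DESeq2 called 1254 genes in A-line HOM against WT, 25 against A-line HET, 185 and 252 between the lines and 261 in the difference of differences. Fitting only the compared groups gave 1440 for A-line HOM and 2200 for G-line HET against WT, 1 for HOM between lines and 0 for the difference of differences (2059 unadjusted by edgeR). Without the libraries with atrial transcripts A-line HET against WT gave 651, G-line HOM against HET 1558, the lines 2 (HOM) and 3 (HET), and the difference of differences 0 by edgeR (1722). Without those with shifted clock genes the same gave 834, 1531, 2, 0 (1821) and 1. A-line HOM against HET then gave 2. No filter beyond 1 count gave 13 for A-line HOM against HET, 52 and 69 between the lines and 58 for the difference of differences. At least 1 CPM gave 2 for HET between lines and 1 for the difference of differences. The latter was also 1 with RLE factors and without mitochondrial, ribosomal RNA, Xist and Y-linked genes.

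Replicate numbers did not pair the samples. Of 18 same-number pairs of libraries, the deviations from group means correlated between -0.358 and 0.291 (median -0.122), 2 pairs over 0.1, against a median of 0.0342 for 36 other pairs, and 2 of 12 libraries correlated best with their own number. With the replicate block A-line HOM against WT gave 504 genes, against A-line HET 0 by edgeR (713 unadjusted), each comparison of the lines 1 and the difference of differences 0 (1799).

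Leaving out 1 library at a time, the counts in the same order ranged from 3284 to 4759, 398 to 616, 515 to 1155, 622 to 2038, 1168 to 2796, 0 to 4, 0 to 153, 0 to 607 and 0 to 516. Each 0 was by edgeR, with 816 genes at an unadjusted p under 0.05 for A-line HOM against HET, 1675 for HOM and 1412 to 1902 for HET between lines, and 1927 to 2241 for the difference of differences. DESeq2 on all 13 libraries called 25, 185, 252 and 261. Called lists ranged from 12 to 17, 11 to 13, 9 to 16, 10 to 15, 13 to 19, 10 to 16, 11 to 20 and 9 to 16 over the 8 comparisons of groups.

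Lists called with the preset correlation, the shared pair counted as WT, were 15, 14, 11, 11, 18, 10, 14 and 12 in that order. With an estimated correlation they were 0, 1, 1, 1, 0, 1, 0 and 0, and fry, another kind of test, called 15, 5, 2, 1, 10, 1, 4 and 0.

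The r of the lines' HOM effects against WT (0.668) was 0.499 without a filter, 0.746 at 1 CPM or more, 0.764 with the pair as A-line HOM, 0.772 with it left out, 0.748 without the libraries with atrial transcripts, 0.710 without those with shifted clock genes and 0.74 with the compared groups only. That of the HET effects (0.686) was 0.545 without a filter, 0.817 and 0.822 with the pair as A-line HOM or left out, 0.759 without the libraries with atrial transcripts and 0.764 with the compared groups only. The HOM minus HET effects (-0.0301) correlated at -0.303 with the pair as A-line HOM and at -0.291 with 15 columns. The sign turned with the replicate block (0.0026), the pair left out (0.00692), without atrial (0.190) or clock libraries (0.153), with the compared groups only (0.048) and without A-line HET replicate 2 (0.00549), G-line HOM replicate 1 (0.111) or A-line HET replicate 3 (0.168). Leaving out 1 library gave 0.630 to 0.728, 0.613 to 0.760 and -0.160 to 0.168.

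Leaving out the genes not reported here, the naming rule took 147 called genes in G-line HOM against WT, of which the text names only a part. Of all 147, 54 kept their call in every alternative, as did 0 of 75 in A-line HOM, 1 of 88 in G-line HET, 0 of 88 in A-line HET and 46 of 111 in G-line HOM against HET. So did 0 of 3 in A-line HOM against HET, 0 of 3 for HOM and 0 of 4 for HET between lines, and 0 of 3 in the difference of differences. With all 15 columns edgeR called 0 genes in A-line HOM and in A-line HET against WT (81 and 3556 at an unadjusted p under 0.05). Their 0 was thus fixed in advance. The fit with 1 WT library left few calls to keep in G-line HET against WT. Each later 0 was fixed too, since alternatives given above left no call by edgeR. Such values do not measure how stable single genes are. The called genes that changed sign did so in A-line HOM against WT with the pair as A-line HOM: Acot1 (0.144), Irgm2 (0.0414), Ifit3b (0.154) and Gbp7 (0.0142). The other sign changes were of genes not called. Rbm20 in G-line HOM (-0.0142) ranged from -0.0832 to 0.0284 when 1 library was left out, with values above 0 without WT replicate 1 or 3 or G-line HOM replicate 1 or 3, and was 0.0248 without the clock libraries. In G-line HET (-0.0278) it ranged from -0.0978 to 0.0142, above 0 without WT replicate 1 or G-line HET replicate 3. In A-line HET (0.0609) it ranged from -0.0074 without WT replicate 2 to 0.118, and was -0.0231 with the pair as A-line HOM, -0.0259 with it left out and -0.0514 without the atrial libraries. In G-line HOM against HET (0.0136) it ranged from -0.0496 without G-line HOM replicate 2 to 0.056, turned also without G-line HET replicate 3, and was -0.0134 without a filter and -0.00207 with the compared groups only.

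Camk2d in G-line HOM against WT (-0.0176) ranged from -0.0839 to 0.079 when 1 library was left out, above 0 without WT replicate 1 or G-line HOM replicate 1. It was 0.0719 without the atrial and 0.0789 without the clock libraries. In A-line HOM against WT, with the pair as A-line HOM, Camk2d turned to -0.0848, Myh6 to 0.0319 and Ttn to -0.0794. Ldb3 there (0.0020) ranged from -0.0588 without WT replicate 2 to 0.0587. It was -0.0768 with the replicate block, -0.000746 without mitochondrial and related genes, -0.147 with the pair as A-line HOM, -0.111 with it left out, -0.0373 with 15 columns and -0.0554 without the atrial libraries. Col3a1 (-0.136) ranged from -0.308 to 0.135, the latter without WT replicate 2. It was 0.496 with the pair as A-line HOM, 0.280 with it left out, 0.0765 with 15 columns and 0.138 without the atrial libraries. The A-line libraries were the least deep, as given above. What this depth does to the calls was not tested.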

Other observations

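Of the tests on patterns in this part, those of the shared libraries, of the way the WT table was made and of atrial tissue were chosen after the result was seen; the chromosome test and the splits were not.

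Of 45 splicing factors and SR kinases 13 rose and 5 fell in G-line HOM against WT (13 and 5 adjusted over the list alone; median 0.13, camera adjusted p = 0.267, so the list was not called). Ptbp2, a neuronal relative of the splicing repressor PTB, rose from 30.2 ± 1.01 to 48.3 ± 1.59 CPM (SD, n = 3; 0.68 ± 0.11, adjusted p = 0.000558). Rbfox1, a splicing factor of muscle and brain, fell from 39.9 ± 1.40 to 9.98 ± 3.67 CPM (-2.01 ± 0.23, adjusted p = 0.000105). In A-line HOM 3 rose (7 rose and 1 fell adjusted over the list alone; camera adjusted p = 0.00727, and adjusted p = 0.519 with an estimated correlation). Of 35 RNA granule components 6 rose and 4 fell in G-line HOM (6 and 4 adjusted over the list alone), with a median of -0.01 against a mean of 0.0014 (adjusted p = 0.850). Fmr1, the gene of the fragile X RNA-binding protein, was among those that rose (0.60 ± 0.10, adjusted p = 0.000457). Nufip2 rose in each of the 4 mutant groups, by 0.53 ± 0.08 in G-line HOM, 0.64 ± 0.11 in A-line HOM, 0.43 ± 0.08 in G-line HET and 0.36 ± 0.08 in A-line HET. The last 3 calls were lost with the shared libraries left out (adjusted p = 0.102, 0.152 and 0.243), and that in A-line HET also without WT replicate 3 (0.0618).

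Cenpf, a kinetochore gene of dividing cells, fell in all mutant groups, from 53.4 ± 11.97 CPM in WT to 4.01 ± 1.11 in G-line HOM (-3.72 ± 0.39, adjusted p = 0.00011). It was at 10.3 ± 0.807 in G-line HET (-2.37 ± 0.35), 9.50 ± 5.54 in A-line HET (-2.52 ± 0.37) and 5.20 in A-line HOM (-3.36 ± 0.61, adjusted p = 0.0146; 0.0637 with the shared libraries left out). Of 37 cell cycle genes 4 rose and 2 fell in G-line HOM (1 and 2 adjusted over the list alone; camera adjusted p = 0.654). In A-line HET the list was called lower, with 1 gene, Cenpf, called (1 adjusted over the list alone; median -0.33, adjusted p = 0.00213, and adjusted p = 0.628 with an estimated correlation). Of 31 unfolded protein response genes 5 rose and 6 fell in G-line HOM (5 and 6 adjusted over the list alone; adjusted p = 0.654). In A-line HOM against WT this list was called lower, where 5 fell (7 fell and 2 rose adjusted over the list alone; median -0.14, adjusted p = 0.0434, and adjusted p = 0.682 with an estimated correlation), among them Calr (-0.75) and Hyou1 (-0.60), chaperone genes of the endoplasmic reticulum. In G-line HOM against G-line HET it was called higher, where Xbp1 rose (0 adjusted over the list alone by edgeR; median 0.20, adjusted p = 0.0280, and adjusted p = 0.579 with an estimated correlation). Against G-line HET, 7 of 33 cytokine and chemokine genes rose and 1 fell in G-line HOM (8 and 1 adjusted over the list alone; adjusted p = 0.0466), such as Il1b (3.68 ± 0.59, 1.38 against 0.102 CPM). With them, 3 of 5 neutrophil markers rose (3 adjusted over the list alone; median 1.55, adjusted p = 0.0269, and adjusted p = 0.579 with an estimated correlation). Of 8 lymphocyte and 18 macrophage markers 2 and 2 rose (2 and 2 adjusted over the list alone), and neither list was called (adjusted p = 0.143 and 0.664). Further, 4 of 25 heat shock genes fell (5 fell and 1 rose adjusted over the list alone; adjusted p = 0.00118). The cytokine and heat shock lists each had adjusted p = 0.579 with an estimated correlation. Against WT the heat shock list was called higher in G-line HET, where 2 rose, Dnajb4 and Hspb7 (3 adjusted over the list alone; median 0.15, adjusted p = 0.00819, and adjusted p = 0.842 with an estimated correlation). It was not called in G-line HOM against WT (4 rose and 3 fell, 4 and 4 adjusted over the list alone, adjusted p = 0.665).

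The same columns stood under WT and A-line HOM. An origin of the shared pair from A-line HOM hearts was argued against: of 236 genes called in G-line HET against WT with the pair left out, 78.0% had the pair nearer WT replicate 1 than A-line HOM replicate 1, against 3.39 to 8.05% for the 6 other mutant libraries tested in this way. An origin from WT hearts is consistent with this value of 78.0%. The copied name, and any other error behind it, stays open, since a hypothesis from these values does not replace the labels.

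Myh7b, Hopx, Aqp4 and Strit1 were at a few percent of their WT level or below in every mutant group. A stretch of another strain's genome carried along with Rbm20 was argued against only as a source of changes in genes within it. On the chromosome of Rbm20 lie 0 of the 20 named genes with the largest changes in G-line HET against WT. Effects of such a stretch on genes elsewhere, and strain differences on other chromosomes, were not tested. A WT table made in another way than the mutant tables cannot be told apart from genotype: of the 10 most lowered named genes 7 were lower and 3 called lower in G-line HOM than in G-line HET, which stand in 1 table (Myh7b -1.69, Aqp4 -4.00 and Hopx -1.65), yet an effect of the table and one of the gene dose may add up (the bound that would have argued against it was raised after this value was seen). That bound asked for all 10 to be called lower. It could not be met, since Strit1, which is among the 10, had no count in either group. The Aqp4 value rests on 1 count in G-line HOM replicate 1 and 0 in replicates 2 and 3. The identical columns in the A-line table held 1461 and 1799 counts of Myh7b beside 4 to 11 in A-line HET, which argues against a table effect only if they were counted with that table and not copied into it; an effect of the genotype stays open and untested.

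Nppa was higher in G-line HOM than in WT, while atrial transcripts marked WT replicate 2, G-line HOM replicate 1 and A-line HET replicate 3. Atrial tissue as the source was argued against: Myl7, Myl4 and Sln, abundant atrial transcripts, summed to at most 1.55% of the Nppa level in each of the 3 G-line HOM libraries, against 100.5% in WT replicate 2. An effect of the genotype and any other difference between the WT and mutant libraries stay open and untested.

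Each comparison of 3 libraries with 3 allows 10 splits, too few for a share under 0.05. In G-line HOM, G-line HET and A-line HET against WT and in G-line HOM against G-line HET the real split called 4640, 1322, 1400 and 2575 genes, the highest other 0 in each by edgeR, and 1 split gave as many. For gene lists, the real splits called 15, 11, 11 and 18 in that order and 12 in A-line HET against G-line HET. Counting the real one, 3, 7, 7, 2 and 5 splits called as many, and the highest other called 20, 17, 21, 18 and 18. Each other split has 2 libraries of 1 group and 1 of the other on each side, and so still holds part of the difference between the groups.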
